A study of Mus musculus with 4 samples.

How the data were processed

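NK cells were enriched from mouse spleen with negative selection beads and sorted, and single-cell libraries were made with the 10x Genomics 3′ kit (V3 chemistry), per the labels' protocols. In this method each cell's RNA is tagged in a droplet with a 16-base barcode, and reads come from the 3′ ends of transcripts. Cell Ranger 3.1.0, Seurat 3 and the build mm10 are named in the submitters' processing notes; the annotation release, the cell-calling settings and the read-depth setting of the aggregation are not given in the sources used here. The deposited files used were a table naming the 4 aggregated libraries, the list of cell barcodes that passed the authors' filter, and the table of counted genes with gene ID, symbol and feature type. All of these are names, not measurements. A counted gene here is one with an entry in the table of counted genes, whether or not any of its transcripts was detected. UMI counts were not analysed here, so the total count per library and the depth behind each barcode are unknown.

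Each library name in the aggregation table carries the genotype and infection words of 1 sample's label. Each barcode ends in a number from 1 to 4. This was read as the row of the aggregation table, which is how Cell Ranger numbers aggregated libraries; the files do not state it themselves, and every value given per library rests on it. Each group had 1 library, so leaving out replicates did not apply. Each factor was also tested over the 2 pairs of libraries that differ in it alone, with an exact sign-flip permutation test of the mean log2 ratio, added after seeing the data. Doublets were not called, since that needs UMI counts. The expression and clustering comparisons planned for a count matrix were not run.

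Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. Numbers of barcodes have 95% exact Poisson intervals, ratios of 2 such numbers exact conditional binomial intervals, and shares exact Clopper-Pearson intervals; all cover counting error only. Barcode sequences listed in both libraries of a pair were counted for the 6 pairs and compared with the hypergeometric expectation under equal use of the list of the kit, which is known from the kit and not from the files, with exact two-sided p-values adjusted by Benjamini-Hochberg. The 6 ratios were compared with each other by chi-square, with p from multinomial draws of the observed total, a test added after seeing the data. Near-identical barcodes were pairs at Hamming distance 1. On simulated libraries of the same sizes drawn from a pool of known size, the median of the estimated over the true pool size was 1.00 in 100 draws, 96% of the intervals held the true size. In 100 draws from a list of the size of the kit list with carried-over barcodes planted in each of the 6 pairs, the test called 0.833% of pairs with none planted, 4.50% with 5, 50.8% with 10, 98.5% with 20 and 100% with 40 planted per pair. With 10 planted the lowest pair, both control libraries, was called in 28% of draws. These draws used the same list size that the test assumes. The shares called therefore do not apply to the data if the pool in use was smaller than the kit list.

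Gene IDs were matched without version to GENCODE mouse release M21, which is on GRCm38, the assembly that mm10 names; coordinates are from that release and count from 1. It was not shown to be the release the authors used: 42 of 31053 IDs were not found in it, and 30541 of the 31011 found had the same symbol. The rule for named genes, fixed before the data were examined, was Cox10 and the members of the fixed lists, described by presence only; genes named as sharing sequence, the antisense genes at the Cox10 locus and the NK receptor families were added after seeing the data. For the search of 3′ ends, the last 400 bases of each GENCODE basic transcript with a complete 3′ end were cut into 91-base stretches, 91 being an assumed read length since none is given in the sources used here. Cox10 was the only gene searched without a basic transcript marked as complete at its 3′ end, and its basic transcript was used. A stretch was called shared where it occurred exactly in an annotated transcript of another gene, leaving out genes that overlap the same strand and are not in the table of counted genes. Unannotated copies in the genome were not searched. Alternatives tried were another expectation for shared barcodes (a pool size estimated from the 6 pairs, matching on GC count, 1 mismatch, 0.5 of the list), leaving out shared or near-identical barcodes, Hamming distance 2, symbols matched ignoring case, stretches of 50 bases and the last 200 bases.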

Results

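The study profiled single natural killer (NK) cells sorted from mouse spleen, comparing wild-type animals (labelled RosaWT) with Cox10 knockout animals (labelled Cox10KO). Both genotypes were sampled without infection and with murine cytomegalovirus (MCMV) infection. The label Cox10KO does not say in which cells the gene was deleted. Cox10 is the farnesyltransferase that makes heme O, a precursor of the heme A of cytochrome c oxidase (complex IV of the respiratory chain). NK cells are innate lymphocytes that expand in response to MCMV, and the series title places the question there: whether Cox10 is needed for NK cell expansion and memory after viral infection. There were 4 libraries, 1 for each combination of genotype and infection, so no group had a replicate. The values examined were the cell barcodes that passed the authors' cell calling and the table of genes whose transcripts could be counted. Genes with an entry in it are called counted genes here. An entry does not show that any transcript of the gene was detected. Barcodes were assigned to libraries by their numeric suffix, read as the row of the aggregation table. UMI counts per gene were not analysed here, so no gene, gene group or cell type is reported as higher or lower in any library, and the sequencing depth of each library is unknown.

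In mice without infection, the Cox10 knockout library held 20535 cell barcodes and the wild-type library 10930. The knockout library therefore held 1.88 times as many barcodes (95% exact interval 1.84 to 1.92). With MCMV infection the order was the other way: the knockout library held 6743 barcodes and the wild-type library 8326, a ratio of 0.810 (95% exact interval 0.784 to 0.836). Exact Poisson intervals of the 4 numbers ran from 20255 to 20818 and from 10726 to 11137 without infection, and from 6583 to 6906 and from 8148 to 8507 with infection. These intervals cover counting error only. A number of barcodes also depends on how many sorted cells were loaded, which the labels do not give, and it is not a count of NK cells per spleen. A barcode that held 2 cells (a doublet) counts once, and doublets were not called.

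Within the wild type, the MCMV library held 0.762 times the barcodes of the control library (95% exact interval 0.740 to 0.784). Within the knockout, the corresponding ratio was 0.328 (95% exact interval 0.319 to 0.338). The genotype ratio with infection was 0.431 times that without infection (95% log-normal interval from the 4 counts, 0.414 to 0.448). Each factor could be tested over the 2 pairs of libraries that differ in it alone, a test added after seeing the data. The mean log2 ratio of knockout over wild type was 0.30 ± 0.86 (SD, n = 2 pairs, exact two-sided sign-flip permutation p = 1), and that of infected over control libraries was -0.9996 ± 0.86 (SD, n = 2 pairs, exact p = 0.5). The smallest p that 2 pairs allow is 0.5, so neither difference could pass a threshold of 0.05. The 2 pairs of a test differ in infection or in genotype and are not replicates. Each SD therefore reflects the difference between those pairs and not the spread of replicate libraries. The log2 ratio of knockout over wild type was 0.91 in the control pair and -0.30 in the MCMV pair. The difference between the genotype ratios with and without infection has no residual degree of freedom and was not tested.

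**Figure D1:**
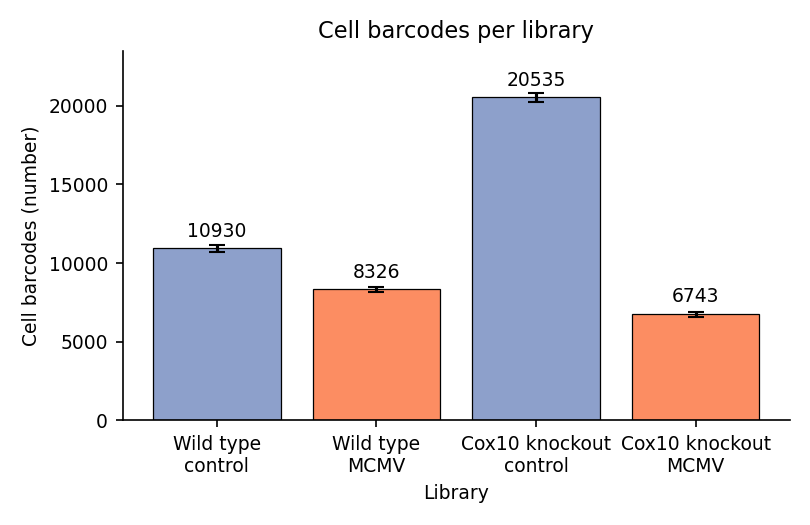
Number of cell barcodes (vertical axis) in each of the 4 libraries (horizontal axis), with 95% exact Poisson intervals as error bars; blue bars are control libraries and orange bars MCMV libraries. The knockout control library, at 20535, lies above the wild-type control at 10930, while the knockout MCMV library, at 6743, lies below the wild-type MCMV library at 8326.

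Whether the libraries were separate from each other was examined by the 16-base barcode sequences listed in more than 1 of them. Of 46331 distinct sequences, 201 were listed in 2 libraries, 1 in 3 and 0 in all 4. In each library the barcodes also listed elsewhere were a small part: 1.06% in the wild-type control (95% exact interval 0.878 to 1.27%), 0.961% in the wild-type MCMV library (0.763 to 1.19%), 0.682% in the knockout control (0.574 to 0.804%) and 1.02% in the knockout MCMV library (0.797 to 1.29%). Summed over the 6 pairs of libraries there were 204 shared barcodes, against 111 expected if each library drew its barcodes at random from the whole list of the kit. The observed number was 1.84 times the expected one (95% exact Poisson interval 1.59 to 2.11, exact two-sided Poisson p = 3.8e-15). The ratio was above 1 in all 6 pairs. The 6 ratios did not differ from each other beyond chance (chi-square 5.87, p = 0.32 from 100000 multinomial draws). In 4 of the 6 pairs the exact two-sided hypergeometric p, adjusted by Benjamini-Hochberg over the 6 pairs, was below 0.05, and the lowest was 1.6e-07 for both control libraries, which shared 70 barcodes. Against an expectation from 0.5 of the kit list, an alternative chosen after seeing the data, the ratio was 0.918 (0.797 to 1.05) and no pair passed the test.

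**Figure D2:**
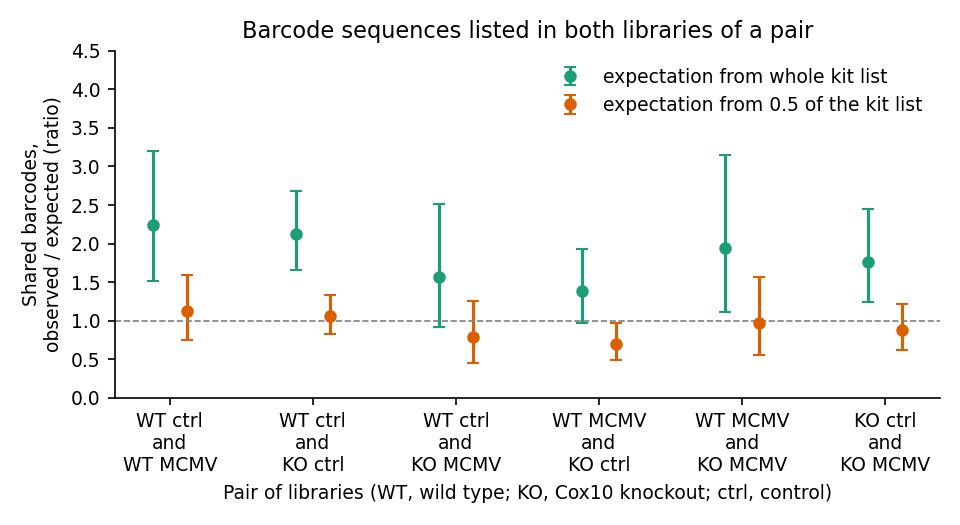
Barcodes listed in both libraries of a pair, as observed over expected number (vertical axis, ratio), for the 6 pairs of libraries (horizontal axis), with 95% exact Poisson intervals; the dashed line marks a ratio of 1. Against the whole kit list (green) all 6 ratios lie above 1, up to 2.24; against 0.5 of it (orange) they run from 0.695 to 1.12.

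No barcode lay at 1 mismatch from another barcode, within a library or between libraries, whereas pairs at 2 mismatches occurred at 8.90 per 1000000 pairs within and 9.08 between libraries. A list of valid barcodes with no such pairs would give this 0 whatever the cells, so it does not measure barcode errors.

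The targeted gene, Cox10 (ENSMUSG00000042148), was in the table of counted genes. It lies on the minus strand of chromosome 11 from 63962627 to 64079468 (mm10), and its main transcript has 7 exons. The last exon, from 63962627 to 63964528, holds the end of the coding sequence and a 3′ untranslated region of 1498 bases as annotated, from 63962627 to 63964124. No Cox10 transcript of the GENCODE basic set is marked as complete at its 3′ end. The place of the poly-A tail, next to which a 3′ kit samples reads, is therefore not known from that set. The antisense gene 9630013K17Rik (chromosome 11, 63964226 to 63968040, plus strand) overlaps the coding part of that exon, and the antisense gene Gm12289 (64012615 to 64015224, plus strand) lies within the Cox10 locus; both were counted genes too. The labels do not say which exon was deleted.

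The table held 31053 genes, each with its own mouse Ensembl ID. No ID came from outside the mouse annotation, so transcripts of MCMV or of a transgene had no entry of their own. By GENCODE release M21, in which 31011 of the IDs were found, 21974 were protein-coding, 5459 lincRNA and 2816 antisense genes. Only 13 of the 37 mitochondrial genes were included, and no gene annotated there as a mitochondrial rRNA or tRNA was among them. The lists fixed before the data were examined held 202 distinct genes in 10 gene lists and 12 marker lists, and 201 of these matched exactly 1 ID. All 20 genes of the complex IV list were present, from the assembly factors Cox15, Sco1 and Surf1 to the mitochondrially encoded subunits mt-Co1, mt-Co2 and mt-Co3, as were all 16 genes of the other respiratory chain list. All 25 genes of the NK receptor and maturation list were present, including Ncr1 (the NK receptor NKp46), Klrg1 (a marker of mature NK cells) and Klra8 (the activating receptor Ly49H, which binds an MCMV protein), as were all 12 NK effector genes. The lists for proliferation (16 genes), interferon response (14), mitochondrial stress (13), survival and death (7) and dissociation stress (7) were also complete. The exception was Aldoa, a glycolytic aldolase, whose symbol was carried by 2 IDs, so 15 of the 16 glycolysis genes matched 1 ID. Those IDs, ENSMUSG00000030695 and ENSMUSG00000114515, are neighbours on chromosome 7 (126795234 to 126800751 and 126800790 to 126809108), and 35 symbols in the whole table were carried by more than 1 ID.

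The last 400 bases of the annotated transcripts of each list gene were searched for 91-base stretches that also occur in transcripts of another gene, a search added after seeing the data. Of 203 IDs, 172 shared none, and 8 shared 50% or more. The 3 mitochondrially encoded complex IV subunits on the list were among those 8. For mt-Co1 100% of the stretches were shared, for mt-Co2 99.0% and for mt-Co3 99.7%, and mt-Atp6, a subunit of ATP synthase, was at 99.0%. The gene sharing most with each was an unprocessed pseudogene on the minus strand of chromosome 1: Gm29216 (24615706 to 24616197), Gm28661 (24614885 to 24615565), Gm28437 (24613189 to 24613971) and Gm10925 (24613974 to 24614651), in the order of the genes above. These 4 pseudogenes were not in the table of counted genes. How reads from shared stretches were counted was not examined, so the percentages are not shares of lost or misassigned reads. Such sharing was not general to mitochondrial genes: of the others listed, mt-Cytb, mt-Nd1 and mt-Nd4 shared no stretch. The gene mt-Nd2 shared 12.6%, or 35.5% with the last 200 bases. The other 4 of the 8 were the glycolytic genes Gapdh (73.0%) and Eno1 (67.1%) and the alpha-globin genes Hba-a1 (70.6%) and Hba-a2 (65.5%). Gapdh shared most with the processed pseudogene Gm7336, which was not a counted gene. Eno1 shared most with Eno1b, and the alpha-globin genes with each other, and these were counted genes. With the last 200 bases Gapdh was at 45.0% and each alpha-globin gene at 29.1%, while Eno1 rose to 97.4% and Cox7c, a nuclear complex IV subunit, went from 33.4% to 97.4%. In the last 400 bases Cox7c shared most with the pseudogene Gm10012, which was not a counted gene. Cox10 shared no stretch with another gene, and neither did any of the 12 NK effector genes, Ncr1 or Klra8. For Cox10 the 400 bases searched end where its basic transcript stops, which is not marked as a complete 3′ end. With 50-base stretches Klra8 shared 15.7%, while Cox10, Ncr1 and the NK effector genes still shared none.

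**Figure D3:**
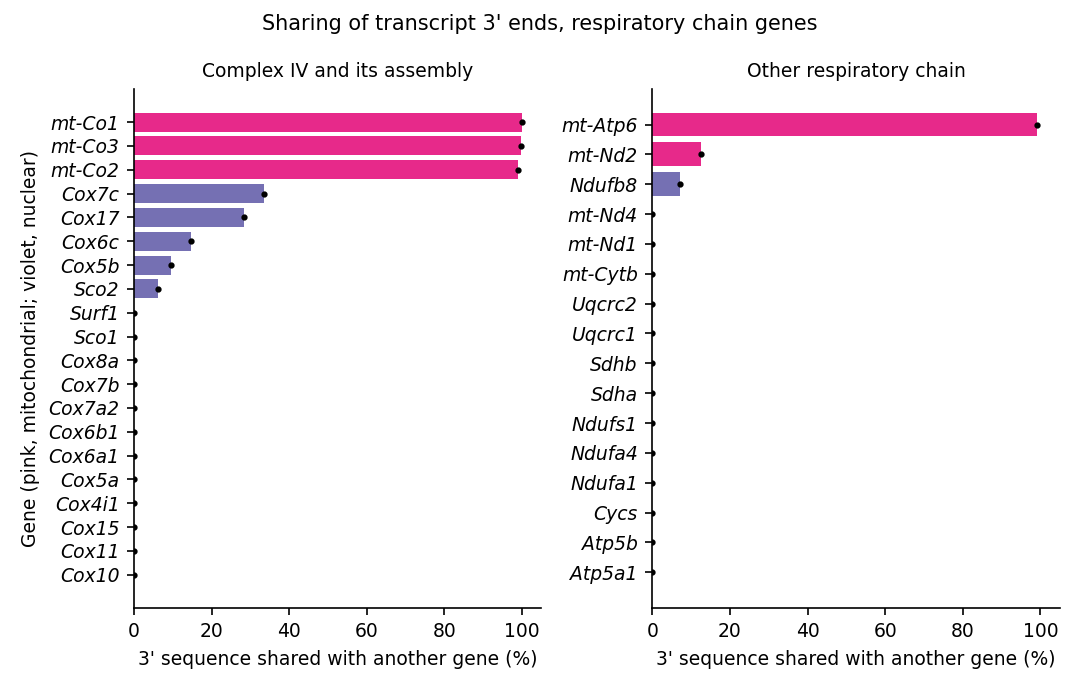
Percentage of the 91-base stretches in the last 400 transcript bases that also occur in another gene (horizontal axis) for each gene (vertical axis) of the complex IV list (left) and the other respiratory chain list (right), with mitochondrial genes in pink and nuclear genes in violet. The genes mt-Co1, mt-Co2, mt-Co3 and mt-Atp6 lie between 99.0% and 100%, and the next highest is Cox7c at 33.4%, or 97.4% when only the last 200 bases are searched.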

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

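Leaving out shared barcodes was decided on before the data were examined, but its use as a test of carry-over, and the tests of loading and of biology, were chosen after the result was seen; the test of barcode errors was written before its own result. The ratio of knockout to wild-type barcodes went in opposite directions in the libraries without and with MCMV: 1.88 without infection and 0.810 with it, so that the latter was 0.431 times the former. With 1 library per group the difference between the conditions was not tested.

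Barcode errors of up to 2 bases that list 1 cell under 2 barcodes are argued against as the whole source of the higher number in the knockout control library. Its excess over the wild-type control was 9605 barcodes, while 3364 of its barcodes had a neighbour within 2 bases. Errors of more than 2 bases were not searched for. Pairs at 2 mismatches were also no denser within libraries (8.90 per 1000000 pairs, 95% exact Poisson interval 8.58 to 9.23) than between them (9.08, interval 8.87 to 9.30). Barcodes carried over and listed in both libraries are argued against as well by their small number. Only 0.682% to 1.06% of the barcodes of a library were listed in another, too few to bring either ratio to the other side of 1. Leaving out all shared sequences therefore adds no separate evidence: it gave 1.89 without infection (interval 1.84 to 1.93) and 0.809 with it (0.784 to 0.836). The number of cells loaded or called and a real difference in NK cell recovery by genotype and infection cannot be told apart, because there was 1 library per group and loaded cell numbers are not in the sources used here.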

How the results depend on the processing

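With shared barcodes left out, the numbers of barcodes and the ratios between libraries stayed within their 95% intervals in 9 of 9 cases. At 0.682% to 1.06% of each library, the barcodes left out were too few to move these values far, so this says little about stability. Counting near-identical barcodes once and allowing 1 mismatch moved nothing, because no barcodes lay at 1 mismatch, and say nothing about stability. The number of list genes matched was the same under matching that ignored case for all 22 lists. The excess of shared barcodes over chance depended on the assumed pool: the overall ratio of 1.84 became 1 by construction with a pool size estimated from the 6 pairs, and 0.918 with 0.5 of the kit list. With the estimated pool the ratio fell below 1 for the wild-type control and knockout MCMV (0.853), wild-type MCMV and knockout control (0.757) and both knockout libraries (0.962); with 0.5 of the list these pairs were at 0.784, 0.695 and 0.883, and both MCMV libraries at 0.968. Matching on GC count changed no call. Barcodes with a near-identical neighbour in their own library went from 0% at 1 mismatch to 9.57% in the wild-type control, 7.39% in the wild-type MCMV, 16.4% in the knockout control and 5.90% in the knockout MCMV library at 2 or fewer. The list genes with 50% or more of the 3′ sequence shared numbered 8, against 11 with 50-base stretches and 6 with the last 200 bases, where Gapdh (45.0%), Hba-a1 (29.1%) and Hba-a2 (29.1%) fell below and Cox7c (97.4%) joined; the cause was not tested. The expression and clustering alternatives were not run, since UMI counts were not analysed here, and depth is unknown.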

Other observations

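The test of complemented positions was written before its result was seen; the search of 3′ ends and the test of barcodes in 3 or more libraries were chosen after seeing the data. The NK receptor families lie together on chromosome 6 and differed in how much of their annotated 3′ ends is unique. The table of counted genes held 11 Klra (Ly49) genes between 129831154 and 131247362, 5 Klrb genes between 128609227 and 129057464, and 3 Klrc (NKG2) genes between 129639064 and 129678973. None of the 5 Klrb genes, which include Klrb1c (NK1.1), shared a 91-base stretch with another gene, and 7 of the 11 Klra genes shared none; with 50-base stretches 4 of 5 and 5 of 11 shared none. Klra10 shared 19.7% of its stretches, the most of them with Klra3, and Klra9 shared 10.1%, the most with the pseudogene Klra11-ps. With 50-base stretches these shares were 52.1% for Klra10 and 41.0% for Klra9, and with the last 200 bases 50.9% and 0%. Klrc1, the inhibitory NKG2A chain, shared 30.1%, the most with Klrc2, the activating NKG2C chain. For Klrc1 the share was 57.5% with 50-base stretches and 25.3% with the last 200 bases. The 3′ untranslated region annotated for the main transcript was 19 bases in Klra10, against 318 in Klra3 and Klra9. In Klrc1 and Klrc3 it was 3 bases. The bases searched in those main transcripts of Klra10, Klrc1 and Klrc3 were therefore largely coding. Their shares may not describe the ends that reads come from.

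Genes of the interferon response list shared no 91-base stretch in 12 of 14 cases, and the exceptions were Oas1a at 23.5%, the most with Oas1g, and Ifit3 at 8.39%, the most with Ifit3b. With 50-base stretches 10 of 14 shared none, and Oas1a was at 43.6% and Ifit3 at 19.1%; with the last 200 bases all 14 shared none. In the proliferation list 14 of 16 shared none, and Ccnb1 (20.7%) and Stmn1 (17.1%) shared most with processed pseudogenes that were not counted genes. With 50-base stretches 12 of 16 shared none, and Ccnb1 was at 34.8% and Stmn1 at 27.3%; with the last 200 bases these were at 1.32% and 4.24%. Of the cell type marker lists, those for NK cells (8 genes), ILC1 (6), T cells (8), B cells (6), plasma cells (4), neutrophils (4), dendritic cells (6), platelets (3), basophils or mast cells (4) and stroma (3) shared no 91-base stretch. With 50-base stretches 6 of 8 T cell genes (all but Cd8b1, 24.5%, and Trbc2, 11.7%), 5 of 6 ILC1 genes, 3 of 4 neutrophil genes and 5 of 6 dendritic cell genes shared none. In the monocyte or macrophage list Ly6c2 shared 17.1%, the most with Ly6c1, and Lyz2 4.52%, the most with Lyz1; with 50-base stretches these were 35.4% and 17.7%, and with the last 200 bases 8.18% and 0%. In the erythroid list 4 of 5 genes shared 91-base stretches, each the most with its own globin neighbour, and 2 of 5 did with the last 200 bases.

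The libraries shared 1.84 times as many barcodes as equal use of the whole kit list gives. A candidate explanation is that only one barcode of each pair on the list, the pairs being known from the kit as complements at positions 8 and 9 counted from the first base, is carried by the oligo that primes poly-A RNA. The pool size estimated from the sharing was 3699686 barcodes (95% interval 3225405 to 4264889), an interval that holds 0.5 of the kit list and leaves out the whole list. Matches between libraries at the complemented positions numbered 32 (95% exact Poisson interval 21.9 to 45.2), below the 111 that a whole list in equal use would give. At 15.7% of the exact matches they missed the 10% bound set beforehand. At the other adjacent position pairs there were 21 to 47 matches in 12 cases (median 33) and 0 at positions 7 and 8 and at positions 9 and 10. All 12 numbers also lay above the bound, so missing it does not set positions 8 and 9 apart. The bound could not decide the question, and the explanation stays open. Reads assigned to the wrong library index and uneven use of barcodes stay open too. For misassigned reads, matches at the complemented positions were predicted beforehand to stay at 111 while the exact matches exceeded that number. With 32 complemented matches that prediction was missed. The miss speaks against equal use of the whole list. Misassigned reads within a smaller pool could not be judged from it. The exact matches were 0.918 times the expectation from 0.5 of the list (0.797 to 1.05), which leaves little excess to explain only if that pool is the right one. For uneven use, 1 sequence was found in 3 libraries, against 0.376 expected from a pool of the estimated size. The least number expected under uneven use was also 0.376, so no count could have argued against it. No biological explanation was tested.

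With a pool of the estimated size, 2 beads of one library carry the same barcode by chance in 57.0 expected cases in the knockout control library (0.278% of its barcodes), 16.1 in the wild-type control, 9.37 in the wild-type MCMV library and 6.14 in the knockout MCMV library.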
